A study of Homo sapiens with 8 samples.

How the data were processed

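RNA was sequenced from MDA-MB-231 cells carrying a stable lentiviral hairpin against YB-1 or a scrambled hairpin, as 3 tumor libraries and 1 library from 2D culture per hairpin. The molecule is given as total RNA, and the libraries were strand-specific and paired-end, per the labels. Tumors were minced and digested with enzymes, and human cells were sorted for EpCAM and CD298 with depletion of mouse cells carrying CD45 or CD31, per the labels. Dissociation itself changes early response genes, so a list of such genes was included. The authors deposited FPKM values (fragments per kilobase of transcript, scaled for depth) for 12299 genes, of which 21 carried a date in place of a symbol. The genome build GRCh37 and the tool DESeq2 are named in the submitters' processing notes without a role. The aligner, the counter, its use of strand, the annotation and the filter on genes are not given in the sources used here. No coordinates are printed, and the neighbour relation of RPPH1 and PARP2 was taken from GENCODE version 29 on GRCh38.

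The deposited FPKM columns summed to 291429 to 1778937, while the median gene stood at 1.38 to 1.46 FPKM in every library. The depth term was therefore not the read total, and the tool and the gene set behind it are not given in the sources used here. A gene's values were whole multiples of 1 step per library, which gave whole reads (within 0.02 of a whole number) for 12286 genes (99.9%). The reads recovered were 7104951 in the shScr 2D library, 6090039, 7680588 and 6188924 in shScr tumors 1 to 3, 10256348 in the shYB-1 2D library and 9012863, 7381348 and 9051597 in shYB-1 tumors 1 to 3. In the same order, 72.1, 46.9, 60.5, 53.3, 61.0, 50.9, 39.7 and 39.5% of them came from the mitochondrial genome, and 642, 119, 165, 172, 296, 48, 102 and 22 genes were listed at 0. Replicates of an arm differed beyond sampling noise (chi-square per gene from 15.3 to 224 over genes with at least 10 reads), so each library counted as 1 sample.

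Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so that fold changes are on the FPKM + 1 scale, which understates the change of genes at low levels. Genes with a mean of at least 1 FPKM over the libraries in a fit were tested with lmFit and eBayes (trend on the mean level), two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Tumors of the hairpins were compared over the 6 tumor libraries. Tumors were compared with 2D culture over all 8 libraries with the hairpin as a covariate, and the difference of the hairpin effect between tumors and culture was tested as an interaction in a fit of the 4 groups. The 2D libraries of the hairpins were compared by their difference of log2(FPKM + 1), with no test. The log2 differences of the hairpins in tumors and in culture were set against each other by Pearson and Spearman correlation across genes. YBX1 was also tested with an exact permutation test. The sample groups, tests, filter, most of the other settings, gene lists and the rule for naming genes were fixed before the data were examined.

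There were 26 gene lists, assembled from general knowledge: YB-1 and cold shock domain family, genes commonly described as YB-1 targets, hypoxia and HIF1 targets, NRF2 and antioxidant response, stress granule components, unfolded protein and integrated stress response, DNA replication and G1/S, mitosis and G2/M, mesenchymal and invasion, epithelial, TGF-beta and YAP targets, interferon response, antigen presentation, inflammatory cytokines and NF-kB, cholesterol synthesis, cytosolic ribosomal proteins, translation initiation and elongation factors, nuclear-encoded respiratory chain, mitochondrially encoded, immediate early and dissociation stress, replication-dependent histones, fibroblast and mural markers, leukocyte markers, endothelial markers, erythroid markers and adipocyte markers. Lists with at least 3 tested genes were tested with limma camera, two-sided, at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 23 lists tested. In addition each member was adjusted over the list alone. In 2D culture, and by a later decision also in tumors, the median of a list was placed among 10000 random lists of the same size, each member replaced by 1 of the 50 genes nearest in mean FPKM. Random lists hold unrelated genes, while genes of a list can move together, so a percentile places a median and is no test.

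Genes were named by a rule: YBX1, then up to 10 genes per direction with the largest log2 fold change that passed, had a mean of at least 5 FPKM in the higher group and showed no overlap between the groups. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not having passed. In 2D culture the 10 largest differences per direction were named, and for the interaction up to 5 per direction. From each list up to 4 members were named, those that passed first and then those with the highest mean FPKM. Ratios of single 2D libraries carry 95% exact intervals from the recovered reads, and a group at 0 was set at a floor of 3 reads per library; both cover counting error only.

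The other settings fixed beforehand were a pseudocount of 0.1 or 5, no filter, a minimum of 5 FPKM, median ratio scaling over the tested genes, a replicate block, no variance trend, an additive fit over all 8 libraries, each arm alone and each library left out in turn. Quantile normalization (also without shYB-1 tumor replicate 3), scaling to equal read totals outside the mitochondrial genome, and voom weights on the recovered reads were added after the data had been seen. Lists of 20 abundant fibroblast and 12 abundant macrophage transcripts were written after the data had been seen and before they were tested. The steps were tested on simulated data with known changes. With 7261 genes in the comparison of shYB-1 with shScr tumors, limma recovered 92.5% of 2-fold changes and all 4-fold and 8-fold changes, with 18 false calls. With 7456 genes in the comparison of tumors with 2D culture it recovered 77.6% of 2-fold changes and all 4-fold and 8-fold changes, with 5 false calls. In both, camera called the 1 shifted list and 0 of the others among 23 lists. Noise in the simulations was drawn independently for each gene, unlike in lists whose genes move together. The spread given to each gene had already been shrunk toward that of other genes. The simulations therefore measure neither how often camera calls lists falsely in these libraries nor what share of real changes limma finds. In the tumor libraries TPM2, at a log2 fold change of -1.60, did not pass (limma adjusted p = 0.159). Recovery of reads was correct for all 2991 simulated genes, up to a whole factor shared by all libraries of a gene. The reads of a gene may be understated by such a factor. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.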

Results

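RNA sequencing was carried out on MDA-MB-231, an established human breast cancer cell line that lacks estrogen receptor, progesterone receptor and HER2. The cells carried a stable lentiviral short hairpin RNA against YB-1 (shYB-1) or a scrambled hairpin (shScr). YB-1, encoded by YBX1, is a cold shock domain protein that binds RNA and DNA. Each hairpin was represented by 3 libraries from tumors and by 1 library from cells grown in 2D culture, 8 libraries in all. Tumor tissue was dissociated and the human cells were collected by sorting on EpCAM and CD298, while mouse cells carrying CD45 or CD31 were depleted, per the labels. Levels were given in FPKM for 12299 genes. The reads recovered from these values numbered 6090039 to 10256348 per library, of which 39.5% (shYB-1 tumor replicate 3) to 72.1% (shScr 2D) came from the mitochondrial genome. Reads of other genes ranged from 1978866 in the shScr 2D library to 5474197 in shYB-1 tumor replicate 3. Nothing in the labels says that the tumor libraries of an arm came from separate animals, so p-values measure only the spread between these samples, which may be technical.

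The first comparison addressed what differed between shYB-1 and shScr tumors, and YBX1 itself served as a check of the labels. No other hairpin against YB-1 is named in the labels. Other differences between the cells carrying each hairpin therefore cannot be told apart from depletion of YB-1. YBX1 fell from 307 ± 66.6 FPKM in shScr tumors to 35.9 ± 11.2 FPKM in shYB-1 tumors (SD, n = 3 each). The log2 fold change was -3.09 (SE 0.33, limma adjusted p = 0.0216), or 8.52-fold lower on the FPKM + 1 scale, and all 3 shYB-1 tumors lay below all 3 shScr tumors. An exact two-sided permutation test of YBX1 gave p = 0.1, the smallest value that 20 arrangements allow. In 2D culture, without replicates, YBX1 stood at 133 FPKM in the shScr library (841 reads) and at 5.32 FPKM in the shYB-1 library (74 reads). That was 24.9-fold lower, with a 95% counting interval of 19.6 to 32.1. The limma call for YBX1 in tumors was lost without shScr tumor replicate 1 (log2 fold change -2.94, adjusted p = 0.123), shScr tumor replicate 2 (-3.07, adjusted p = 0.154) or shYB-1 tumor replicate 1 (-3.26, adjusted p = 0.0572), and over all settings tried the adjusted p ranged from 1.7e-15 to 0.154.

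Beside YBX1, 3 genes passed as lower in shYB-1 tumors and no gene passed as higher. RPPH1, the RNA component of RNase P, which processes transfer RNA precursors, fell from 4901 ± 1425 to 589.8 ± 178 FPKM (log2 fold change -3.07, SE 0.41). PARP2, a poly(ADP-ribose) polymerase that acts in DNA repair, fell from 1236 ± 303 to 184 ± 55.0 FPKM (log2 fold change -2.76, SE 0.37). RPPH1 and PARP2 are adjacent on opposite strands of chromosome 14 in the GENCODE annotation of GRCh38. Whether reads were counted by strand is not given in the sources used here, so the PARP2 value is uncertain. SLC7A5, a transporter of large neutral amino acids, fell from 4.39 ± 0.291 to 1.52 ± 0.305 FPKM (log2 fold change -1.10, SE 0.14). SLC7A5 lies under the minimum level set for naming and was chosen after its values were seen. Each of these 3 genes had a limma adjusted p of 0.0392 and was lower in all 3 shYB-1 tumors than in all 3 shScr tumors (n = 3 each). Among genes that did not pass, POLR2J, a subunit of RNA polymerase II, stood at 9.95 ± 1.95 FPKM in shScr and 4.11 ± 0.660 FPKM in shYB-1 tumors (log2 fold change -1.09). TIMM17B, of the mitochondrial inner membrane translocase, stood at 15.4 ± 1.42 and 7.06 ± 1.18 FPKM (log2 fold change -1.03), and both had an adjusted p of 0.159. The genes with the smallest p among those with higher means in shYB-1 tumors were PTPLAD1 (0.66), FEZ2 (0.70), PVRL3 (0.68), CCDC47 (0.63) and LRRC42 (0.53), with adjusted p from 0.162 to 0.167.

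Of 7261 genes tested in tumors, limma called 0 higher and 4 lower in the shYB-1 arm, while 431 were higher and 1045 lower at an unadjusted p under 0.05. With voom weights on the recovered reads the calls numbered 0 higher and 6 lower. The groups did not overlap at all for 27.7% of the genes tested, 690 with all shYB-1 tumors above and 1323 with all below. Chance gives 10% on average, but genes move together, and abundant genes were shifted as a whole in the shYB-1 tumors. The excess is therefore no count of genes changed one by one. The median log2 fold change of all genes was -0.08. Scaled to equal read totals outside the mitochondrial genome, a setting added after the data were seen, that median moved to 0.29 and 92 genes passed as higher and 21 as lower. No gene passed in either direction without shScr tumor replicate 1, shScr tumor replicate 2 or shYB-1 tumor replicate 1, and without shYB-1 tumor replicate 2 there were 2 higher and 9 lower. Without shScr tumor replicate 3 the calls for RPPH1 and PARP2 ended (both adjusted p = 0.287), and SLC7A5 passed only where shYB-1 tumor replicate 2 was the library left out (adjusted p = 0.048). Over all settings tried the adjusted p ranged from 8.3e-11 to 0.287 for RPPH1, from 5.2e-11 to 0.287 for PARP2 and from 0.0146 to 0.202 for SLC7A5.

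**Figure D1:**
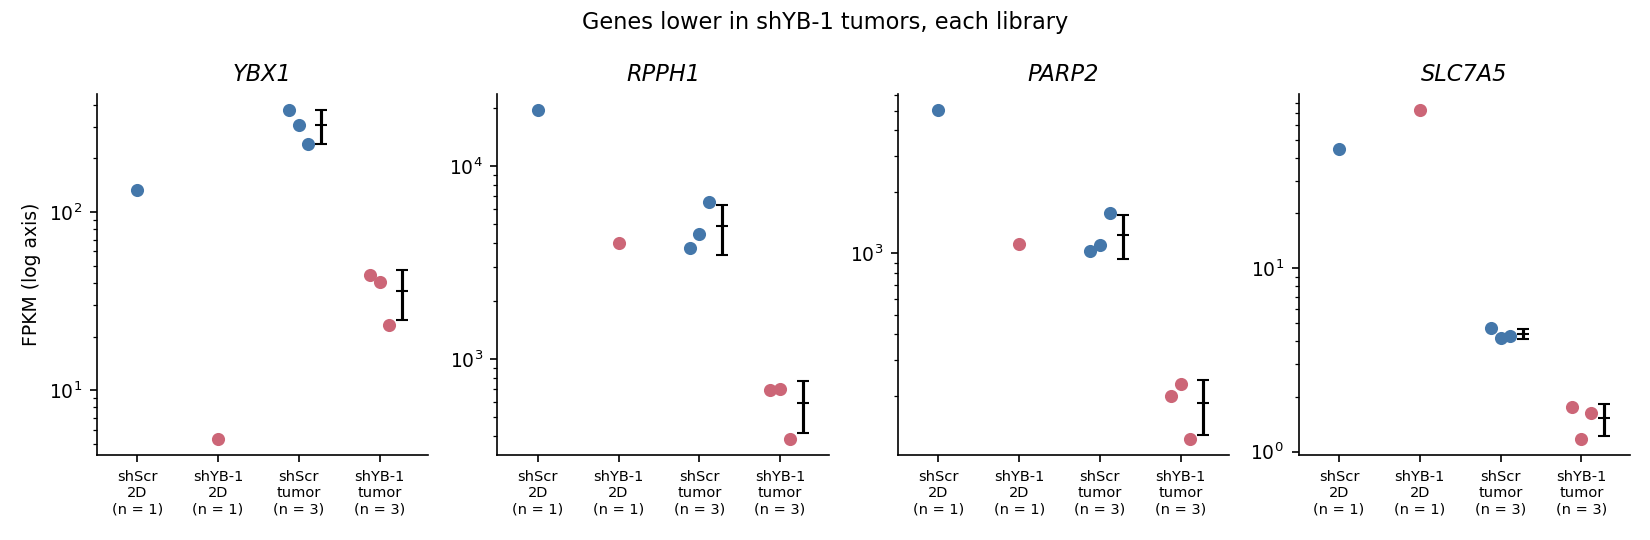
FPKM (log axis) of the 4 genes that limma called lower in shYB-1 tumors, as 1 point per library in the shScr and shYB-1 2D libraries (n = 1 each) and tumors (n = 3 each), with bars for the tumor mean ± SD. YBX1, RPPH1 and PARP2 were also lower in the shYB-1 2D library, whereas SLC7A5 stood at 72.9 FPKM there and at 44.6 FPKM in the shScr 2D library.

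Genes of the cytosolic ribosome were lower as a group in shYB-1 tumors. The median log2 fold change of 73 ribosomal protein genes was -0.82 (limma camera adjusted p = 7.2e-12 with a preset correlation), and 3 of them had a value above 0. With an estimated correlation between genes the adjusted p = 0.88, as it did for each of the 5 lists called in this comparison. No ribosomal protein gene passed over all genes tested, and adjusted over the list alone 0 were higher and 2 lower. RPS18 stood at 5358 ± 671 FPKM in shScr tumors and 2772 ± 247 FPKM in shYB-1 tumors (SD, n = 3 each), RPLP1 at 2311 ± 20.0 and 1319.6 ± 41.6 FPKM, and RPS16 at 2059 ± 28.2 and 944 ± 293 FPKM. Many ribosomal protein genes have near-identical pseudogenes, so their single values are uncertain. At the preset correlation the list kept its call under every setting tried, with camera adjusted p from 3.6e-36 to 7.3e-05. Its medians ranged from -1.02 (without shYB-1 tumor replicate 2) to -0.26 (quantile normalization). Of the 10 splits of the tumor libraries into 3 and 3, 5 called the list at that correlation, the real one among them. Calls at that correlation therefore do not by themselves set the hairpins apart. With equal read totals outside the mitochondrial genome the median was -0.35, and the adjusted p with an estimated correlation was 0.0133, against 0.88 at the highest over all settings tried.

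On the scale of the deposited values, abundant transcripts in general had lower levels in the shYB-1 tumors, to an extent that differed between libraries; quantile normalization removes such a trend by construction. Among 258 genes with a mean of at least 100 FPKM, the median log2 difference from the shScr tumor mean was -1.29 in shYB-1 tumor replicate 3, -0.60 in replicate 1 and -0.25 in replicate 2, and between -0.03 and 0.04 in the shScr tumors. The depth factor of the deposited values had the same order, at 2.76, 1.55 and 1.18 in shYB-1 tumor replicates 3, 1 and 2. It was 0.77 to 0.84 in shScr tumors. Reads outside the mitochondrial genome numbered 4429054 to 5474197 in shYB-1 and 2887283 to 3234617 in shScr tumors. Depth and its scaling therefore cannot be told apart from the hairpin here. Random lists matched to the ribosomal protein genes in mean FPKM had a median of -0.55, with 95% of them between -0.65 and -0.46, above the -0.82 of the ribosomal list. The 13 genes of the mitochondrial genome, which encode subunits of the respiratory chain and ATP synthase, had a median of -1.04 (adjusted p = 0.0245; adjusted p = 0.88 with an estimated correlation), within the -1.11 to -0.70 of their matched lists. MT-CO1 stood at 87048 ± 27516 FPKM in shScr tumors and 39214 ± 14577 FPKM in shYB-1 tumors (SD, n = 3 each), and no member passed, also when adjusted over the list alone. The mitochondrial median was 0.02 under quantile normalization, and without shScr tumor replicate 2 it was -0.82 with the call lost (adjusted p = 0.0997, with a range of 6.7e-06 to 0.867 over all settings tried).

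**Figure D2:**
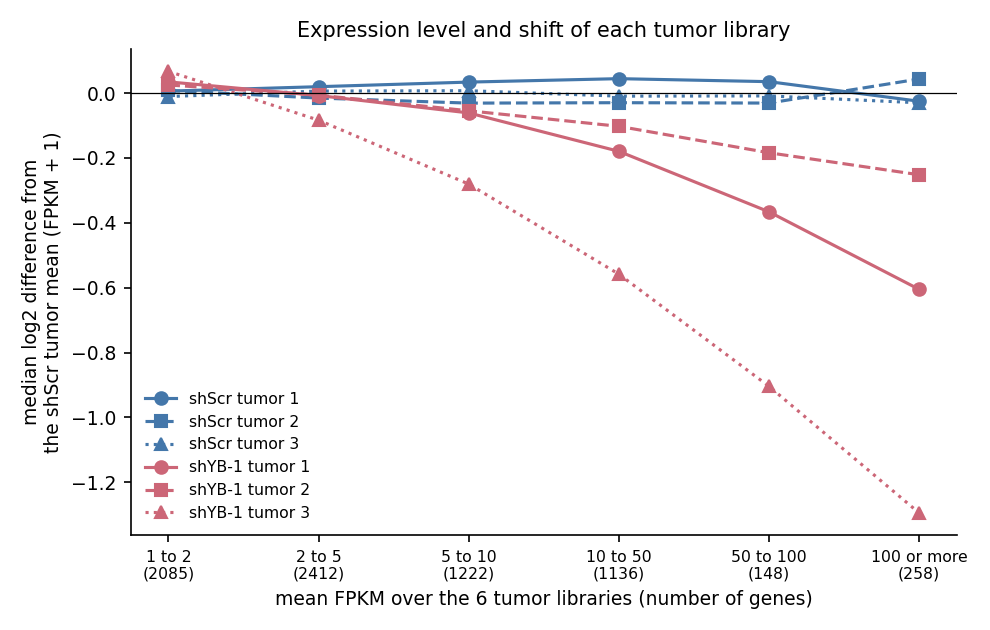
Median log2 difference (FPKM + 1) of each tumor library from the shScr tumor mean, for genes grouped by their mean FPKM over the 6 tumor libraries, with 1 line per library and the number of genes under each group. In the group of at least 100 FPKM the shYB-1 tumors lie at -1.29, -0.60 and -0.25 (replicates 3, 1 and 2), below the shScr tumors.

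The other 3 lists called in tumors had smaller medians. Antigen presentation genes, which load peptides onto HLA molecules, were lower (17 genes, median -0.48, adjusted p = 0.036; adjusted p = 0.88 with an estimated correlation). HLA-B stood at 1697 ± 403 FPKM in shScr and 983 ± 373 FPKM in shYB-1 tumors (SD, n = 3 each) and B2M at 696 ± 41.8 and 528 ± 201 FPKM; values of single HLA genes are uncertain because the family shares near-identical sequence. Adjusted over the list alone, 1 member was lower, TAPBP, the peptide-loading chaperone tapasin (log2 fold change -1.05). Nuclear-encoded respiratory chain genes were lower (38 genes, median -0.26, adjusted p = 0.036; adjusted p = 0.88 with an estimated correlation), but the median was 0.17 with equal read totals, where that of all genes was 0.29. COX8A, a subunit of cytochrome c oxidase, stood at 190.3 ± 26.6 and 106 ± 29.3 FPKM. Hypoxia and HIF1 target genes were called higher over the 3 tumors of each arm (29 genes, median 0.20, mean 0.09, adjusted p = 0.036; adjusted p = 0.88 with an estimated correlation), and no member of the respiratory chain or hypoxia list passed, also when adjusted over the list alone. The hypoxia median relative to the shScr tumor mean was -0.32, 0.92 and -0.29 in shYB-1 tumor replicates 1, 2 and 3 and -0.20 to 0.19 in shScr tumors. Replicate 2 alone of the shYB-1 tumors lay above them and the others lay below. The most abundant hypoxia gene, that of the glycolytic enzyme GAPDH, had a lower mean in shYB-1 tumors (4072 ± 808 FPKM in shScr, 2498 ± 2696 FPKM in shYB-1). The hypoxia markers NDRG1 and CA9, chosen after their values were seen, stood at 384 and 26.1 FPKM in shYB-1 tumor replicate 2, against 24.2 to 52.7 and 3.85 to 8.64 FPKM in the other tumors.

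Against lists matched in mean FPKM, the antigen presentation median lay at percentile 16.6, within the -0.58 to -0.14 that held 95% of them, and the respiratory chain median at percentile 24.5, within -0.34 to -0.09. Neither lay outside the range of other genes of its level. The hypoxia median lay above its matched lists (-0.36 to -0.05), which hold unrelated genes and do not reflect genes that move together. Under quantile normalization the antigen presentation median was -0.09 (adjusted p = 0.542) and the respiratory chain median -0.04 (adjusted p = 0.457), both without a call. With equal read totals outside the mitochondrial genome they were -0.02 (adjusted p = 0.0038, below the median of all genes; adjusted p = 0.732 with an estimated correlation) and 0.17 (adjusted p = 0.0798, no call). At a minimum of 5 FPKM the hypoxia median was -0.15 (adjusted p = 0.208). Each of these 3 calls also ended when certain single libraries were left out. The hypoxia median was -0.34 without shYB-1 tumor replicate 2 (adjusted p = 0.0977), and its call also ended without shScr tumor replicate 1 (0.18, adjusted p = 0.147) or 3 (0.21, adjusted p = 0.121). The antigen presentation call ended without shScr tumor replicate 2 (-0.48, adjusted p = 0.0997) or 3 (-0.38, adjusted p = 0.121) and without shYB-1 tumor replicate 1 (-0.57, adjusted p = 0.0724) or 2 (-0.41, adjusted p = 0.073). The respiratory chain call ended without shScr tumor replicate 1 (-0.24, adjusted p = 0.147) or 2 (-0.30, adjusted p = 0.0949) and shYB-1 tumor replicate 1 (-0.32, adjusted p = 0.0694) or 2 (-0.30, adjusted p = 0.052). Over all settings tried the adjusted p ranged from 1.9e-05 to 0.208 for the hypoxia list, from 0.00335 to 0.542 for antigen presentation and from 4.3e-04 to 0.457 for the respiratory chain. The number of lists called was 5 over all tumors, and 3, 2 and 3 without shScr tumor replicates 1, 2 and 3 and 3, 7 and 10 without shYB-1 tumor replicates 1, 2 and 3.

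The remaining 18 lists with at least 3 measured genes did not pass in tumors, with adjusted p from 0.0784 to 0.785. Median log2 fold changes were -0.05 for mitosis genes, -0.12 for DNA replication genes, 0.11 for replication-dependent histones, -0.04 for stress granule components and -0.22 for translation factors. They were -0.39 for the antioxidant response, -0.23 for the unfolded protein response, -0.29 for the interferon response, -0.23 for inflammatory cytokines, -0.22 for TGF-beta and YAP targets, -0.24 for cholesterol synthesis and -0.17 for immediate early genes. Mesenchymal genes had a median of -0.07 and epithelial genes -0.09, and markers of fibroblasts and leukocytes -0.11 and -0.17. The YB-1 and cold shock domain family had a median of -0.31 over 4 genes, with YBX1, the target of the hairpin, as the member that passed. That median lay at percentile 49.7 of lists matched in mean FPKM, and any call of this list as lower includes the knockdown itself. Genes commonly described as YB-1 targets had a median of -0.05 and a mean of 0.05, and the test, which ranks a list against all other genes, pointed upward. It also pointed upward for the stress granule, mitosis, mesenchymal, epithelial and fibroblast lists, whose medians were below 0. With equal read totals outside the mitochondrial genome, where the median of all genes was 0.29, every one of these medians below 0 was above 0, from 0.06 for the antioxidant response to 0.40 for mesenchymal genes. Adjusted over the list alone, EGFR, the epidermal growth factor receptor, was higher (0.63), as was FOS (1.31), a subunit of the AP-1 transcription factor. Lower on the same basis were ISG15 (-0.98) of the interferon list, CEBPB (-0.92) and DDIT3 (-0.54) of the stress response list, EIF4EBP1 (-0.83), and FOSL1 (-0.88), JUND (-0.86), IER3 (-0.88) and HSPA1B (-1.19) of the immediate early list. None of these members except YBX1 passed over all genes tested. The endothelial, erythroid and adipocyte marker lists had fewer than 3 measured genes and were not tested.

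Of these 18 lists, 10 passed under at least 1 other setting. Genes commonly described as YB-1 targets were called higher under quantile normalization (0.20, adjusted p = 0.0291; adjusted p = 0.86 with an estimated correlation) and with equal read totals outside the mitochondrial genome (0.37, adjusted p = 0.0352; adjusted p = 0.896 with an estimated correlation), with a range of 0.0173 to 0.418 over all settings tried. Mesenchymal genes were called higher under quantile normalization (0.29, adjusted p = 0.00877; adjusted p = 0.86 with an estimated correlation) and without shYB-1 tumor replicate 3 (0.28, adjusted p = 0.0207; adjusted p = 0.677 with an estimated correlation), with a range of 1.3e-04 to 0.686, and their median of -0.07 lay above the -0.60 to -0.17 of lists matched in mean FPKM. Fibroblast and mural markers were called higher without shYB-1 tumor replicate 3 (0.38, adjusted p = 0.0221; adjusted p = 0.677 with an estimated correlation), with a range of 0.0115 to 0.95. Their median differences from the shScr tumor mean were 0.33, 0.41 and -0.78 in shYB-1 tumor replicates 1, 2 and 3, and those of mesenchymal genes -0.09, 0.47 and -0.51, so the sign of both lists depends on the libraries included. Interferon response genes lay below their matched lists (median -0.29, percentile 1.11, against -0.26 to 0.12), with -0.29, -0.24 and -0.14 in shYB-1 tumors and -0.05 to 0.09 in shScr tumors. Without shYB-1 tumor replicate 3 the interferon response (-0.30, adjusted p = 0.0077; adjusted p = 0.677 with an estimated correlation; range 0.00514 to 0.906), cholesterol synthesis (-0.27, adjusted p = 0.0038; adjusted p = 0.677 with an estimated correlation; range 0.00173 to 0.906) and mitosis lists (-0.17, adjusted p = 0.0477; adjusted p = 0.677 with an estimated correlation; range 0.014 to 1) were called lower. Without shYB-1 tumor replicate 2 the mitosis list was called higher (0.05, adjusted p = 0.0307; adjusted p = 0.824 with an estimated correlation). Without that library the antioxidant response (-0.53, adjusted p = 0.0266; adjusted p = 0.758 with an estimated correlation; range 0.0266 to 0.867), TGF-beta and YAP targets (-0.35, adjusted p = 0.0493; adjusted p = 0.824 with an estimated correlation; range 0.0493 to 0.874), the YB-1 and cold shock domain family (-0.48, adjusted p = 0.0327; adjusted p = 0.824 with an estimated correlation; range 3.2e-04 to 0.236) and translation factors (-0.37, adjusted p = 0.00821; adjusted p = 0.824 with an estimated correlation; range 0.00335 to 0.867) were called lower.

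**Figure D3:**
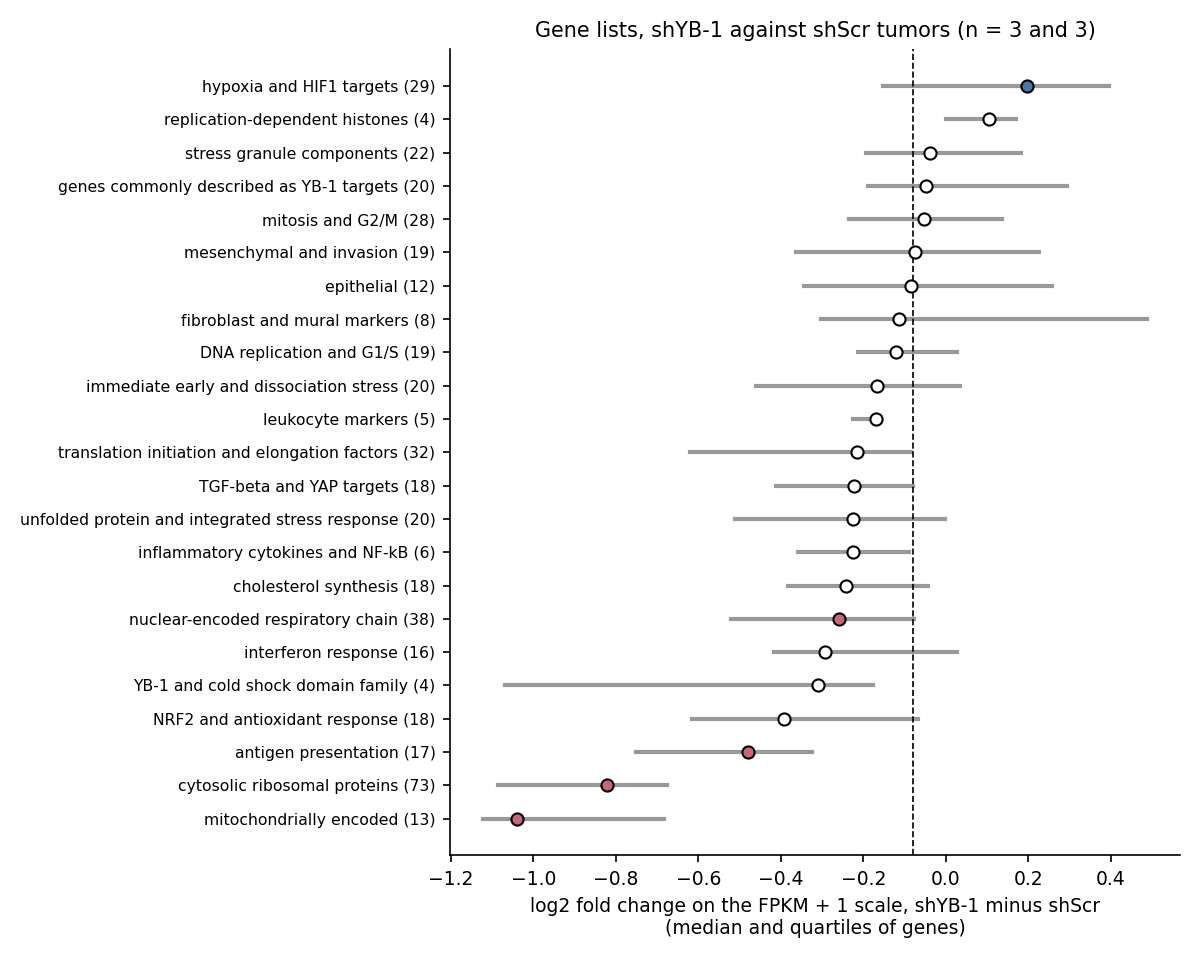
Median log2 fold change (FPKM + 1 scale, points) and quartiles (bars) of the genes of each list, shYB-1 minus shScr tumors (n = 3 each), with the number of genes in brackets and the median of all genes as a dashed line. Filled points mark the 5 lists with a camera adjusted p under 0.05 at a preset correlation, from -1.04 (genes of the mitochondrial genome, 0.02 under quantile normalization) to 0.20 (hypoxia); with equal read totals the respiratory chain median was 0.17.

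The second comparison set the 6 tumor libraries against the 2 libraries from 2D culture, with the hairpin as a covariate. COL1A1, a chain of type I collagen, rose from 0.214 and 0.137 FPKM in 2D culture (shScr and shYB-1, 1 library each) to 115 ± 10.7 and 86.1 ± 45.5 FPKM in tumors (log2 fold change 6.32, SE 0.41, adjusted p = 8.7e-07). SPARC, a collagen-binding matrix protein, rose by 6.20 and COL3A1, of type III collagen, by 4.89 on the log2 scale. Fibroblasts also express COL1A1, SPARC, COL3A1 and BGN at high levels. BGN, the proteoglycan biglycan, was listed at 0 in both 2D libraries and was at least 215-fold higher in tumors, against a floor of 3 reads per 2D library. On the same basis the chemokine gene CXCL14 was at least 99.0-fold, the histone gene HIST3H2A at least 58.0-fold and RP1-146I3.1-201 at least 51.4-fold higher. RPL10L was at least 42.1-fold higher, with an uncertain value because of near-identical copies. ADIRF (5.89), which is active in adipocyte differentiation, and CALB2 (5.72), which encodes the calcium-binding protein calretinin, also rose.

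Of the genes that fell in tumors, SAA1, an acute phase protein, had the lowest log2 fold change on the FPKM + 1 scale (-7.81, SE 0.28, adjusted p = 9.8e-09), from 127 and 407 FPKM in 2D culture to values listed at 0 in 5 tumors and 0.121 FPKM in shYB-1 tumor replicate 3. Others that fell were NNMT (-6.47), nicotinamide N-methyltransferase, the matrix genes COL8A1 (-6.26), EFEMP1 (-5.78) and THBS1 (-5.56), the EGFR ligand AREG (-5.62), the metallothionein MT1X (-5.61), the formyl peptide receptor FPR1 (-5.48) and the adhesion molecule MCAM (-5.34). In all, limma called 1851 genes higher and 1857 lower in tumors among 7456 tested. Both counts were lower in fits that kept only the shYB-1 library from 2D culture than in fits that kept only the shScr library. Such fits set the library that was kept against tumors of the same hairpin alone. The counts therefore depend on the arm, and its 2D library cannot be told apart from its tumors. With equal read totals outside the mitochondrial genome, which moved the median of all genes from 0.03 to 0.35, the counts over all 8 libraries were 2686 higher and 882 lower.

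Of the gene lists, 9 were called between tumors and 2D culture with a preset correlation. All 20 measured genes of the cholesterol synthesis list fell (median -2.49, adjusted p = 8.1e-14; adjusted p = 0.218 with an estimated correlation). DHCR7, an enzyme of the pathway, fell from 125 and 103 FPKM in 2D culture (shScr and shYB-1, 1 library each) to 6.16 ± 1.46 and 3.70 ± 1.05 FPKM in tumors (log2 fold change -4.33). Of 18 TGF-beta and YAP targets 11 fell and 3 rose (median -1.45, adjusted p = 0.00601; adjusted p = 0.612 with an estimated correlation), among them ANKRD1 (-5.05), CYR61 (-4.64) and COL4A2 (-4.00), whereas PMEPA1 rose (3.19). Inflammatory cytokine and NF-kB genes fell in 8 of 10 cases (median -1.34, adjusted p = 1.8e-04; adjusted p = 0.218 with an estimated correlation), with ICAM1 at -3.79, PTGS2, which encodes a prostaglandin synthase, at -3.06 and IL24 at -2.68. In the unfolded protein response list 11 of 20 genes fell and none rose (median -0.74, adjusted p = 0.00601; adjusted p = 0.218 with an estimated correlation), including the chaperone genes HSPA5 (-2.57) and HSP90B1 (-1.89). In the antioxidant list 10 of 20 fell and 3 rose (median -0.57, adjusted p = 0.017; adjusted p = 0.664 with an estimated correlation), with TXNRD1 at -2.26 and SOD1 at 1.05. Of 13 genes of the mitochondrial genome 7 fell (median -1.33, adjusted p = 0.0077; adjusted p = 0.689 with an estimated correlation), with a median of 0.09 under quantile normalization.

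The lists called higher in tumors were fibroblast and mural markers, the interferon response and ribosomal proteins. Of 7 fibroblast and mural markers 6 rose and 1 fell (median 3.20, camera adjusted p = 0.00601 with a preset and 0.612 with an estimated correlation). The log2 fold change was 4.84 for COL1A2 and 3.20 for ACTA2, smooth muscle actin. POSTN was listed at 0 in both 2D libraries and had a fitted value under the median. Its true change may be larger, so the median may be understated. Interferon response genes rose in 9 of 16 cases and fell in 2 (median 0.76, adjusted p = 0.0168; adjusted p = 0.612 with an estimated correlation), with ISG15 at 2.34, IFI27 at 2.24 and IFIT1 at 1.42. Of the ribosomal protein genes 19 rose and none fell (median 0.52, adjusted p = 0.00601; adjusted p = 0.817 with an estimated correlation), with RPL39 at 1.99 and RPS14 at 1.65, and the median was 0.26 without the shScr 2D library. Adjusted over the list alone the counts equalled those over all genes for the cholesterol, TGF-beta, inflammatory, unfolded protein, fibroblast and interferon lists; they were 3 higher and 11 lower for the antioxidant list, 0 higher and 11 lower for the mitochondrial genome and 13 higher and 0 lower for ribosomal proteins. Leukocyte markers and epithelial genes missed the threshold (adjusted p = 0.0508 for both; adjusted p = 0.612 with an estimated correlation). Of 5 leukocyte markers 3 rose, among them CORO1A (2.52) and CSF1R (3.14), the receptor of macrophage colony-stimulating factor, and CD68 fell (-0.94). Of 12 epithelial genes 6 rose, including KRT8 (2.22), JUP (1.73) and EPCAM (1.39), whose protein served in the sort, and 1 fell.

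Some lists without a call held genes that moved in opposite directions. Of 19 mesenchymal and invasion genes 7 rose and 9 fell (median -0.65, mean 0.18, adjusted p = 0.708), with the matrix protein TNC at 3.22, the calcium-binding protein S100A4 at 3.78 and VIM, vimentin, at 2.88, against the lysyl oxidase LOXL2 at -2.39. Among immediate early genes 4 rose and 4 fell (median 0.39, mean -0.03), with KLF2 at 3.06, MYC at -3.27 and DUSP1 at -3.91. The hypoxia list had 7 genes that rose, CA9 (2.46) among them, and 5 that fell, such as the glucose transporter gene SLC2A1 (-2.17). Median and mean also differed in sign for genes commonly described as YB-1 targets (-0.25 and 0.15, with a median of 0.16 under equal read totals) and stress granule components (0.07 and -0.08), and for translation factors the median of -0.04 (0.38 under equal read totals) lay below 0 while the test pointed upward. The lists that did not pass had adjusted p from 0.0508 to 0.968. The 2D side of this comparison holds 1 library per hairpin, and the tumor cells, unlike those in culture, had been through dissociation and sorting.

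**Figure D4:**
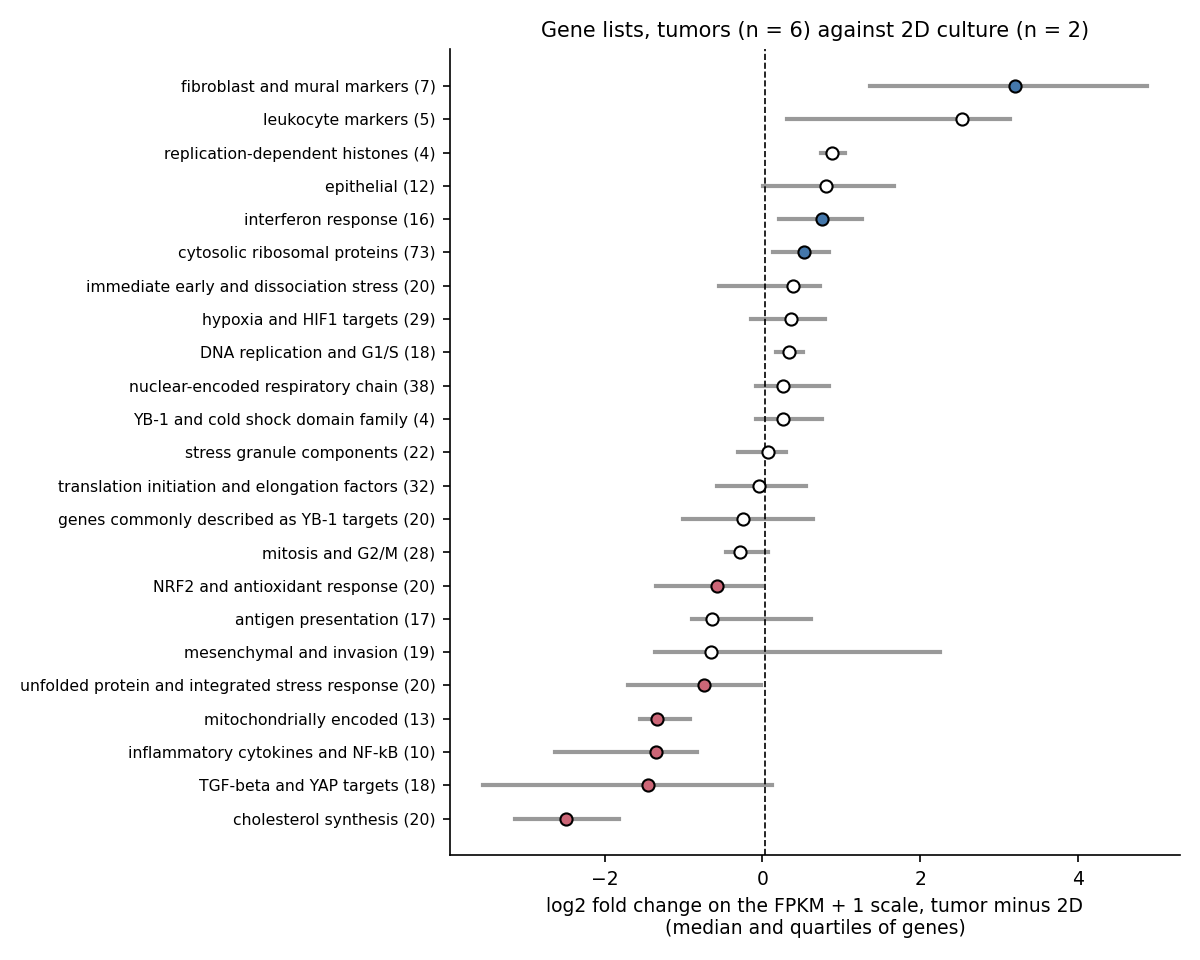
Median log2 fold change (FPKM + 1 scale, points) and quartiles (bars) of the genes of each list, tumors (n = 6) minus 2D culture (n = 2), with the number of genes in brackets and the median of all genes as a dashed line. Filled points mark the 9 lists with a camera adjusted p under 0.05 at a preset correlation, from cholesterol synthesis at -2.49 to fibroblast and mural markers at 3.20; the mitochondrial genome had a median of 0.09 under quantile normalization.

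In 2D culture each hairpin had 1 library, so the differences have no replicate check and describe those 2 libraries. Cell cycle genes were higher in the shYB-1 library. All 28 mitosis genes were above their shScr values (median log2 difference 0.93, percentile 100 among 10000 random lists matched on mean FPKM), with TPX2, a spindle assembly factor, at 52.9 FPKM with shYB-1 and 26.9 FPKM with shScr and CDC20, an activator of the anaphase-promoting complex, at 34.5 FPKM with shYB-1 and 17.5 FPKM with shScr. All 17 DNA replication genes were also higher (median 0.73, percentile 100), with PCNA, the sliding clamp of DNA polymerase, at 23.7 FPKM with shYB-1 and 9.14 FPKM with shScr. Genes commonly described as YB-1 targets had a median of 0.41 (percentile 99.8) and inflammatory cytokine genes of 0.36 (percentile 98.5). The YB-1 target list shares genes such as PCNA and TOP2A with the cell cycle lists, so its median is not independent of theirs. Ribosomal protein genes were lower, 60 of 73 with a median of -0.44 (percentile 0), and RPS18 stood at 3014 FPKM with shYB-1 and 4413 FPKM with shScr. Immediate early genes had a median of -0.46 (percentile 0.0700) and genes of the mitochondrial genome of -0.71 (percentile 1.87), the latter at 0.00 under quantile normalization. Medians of the other lists with at least 3 genes lay between percentiles 6.5 and 95.8. Because the random lists hold unrelated genes while genes of a list can move together, these percentiles are no test.

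Among the largest single-gene differences in 2D culture, HLA-DRA stood at 38.4 FPKM with shYB-1 and 3.50 FPKM with shScr, a ratio with a 95% counting interval of 6.56 to 19.8. HLA-DPA1 was higher by 12.4-fold (4.71 to 46.4), with the 95% counting interval in brackets here and for the following genes. CD74, the invariant chain, was higher by 5.09-fold (4.45 to 5.85), at 175 FPKM with shYB-1 and 34.5 FPKM with shScr. HLA-DRB5 was higher by 14.1-fold (4.69 to 69.8) from 3 reads in the shScr library. The HLA-J pseudogene was higher by 149-fold (41.0 to 1229.5) from 2 reads, and all HLA values are uncertain because of near-identical copies. The antigen presentation list, which holds HLA-DRA and CD74, had a median of 0.02 in 2D culture (percentile 64.1), with 9 genes higher and 8 lower. Others among the largest increases were C15orf48 at 10.5-fold (5.21 to 24.6), ARL6IP1 at 5.73-fold (4.55 to 7.30), the complement component C3 at 15.2-fold (7.58 to 35.5), the heparan sulfate proteoglycan SDC4 at 4.17-fold (3.83 to 4.53) and the glycoprotein hormone STC1 at 4.47-fold (3.45 to 5.89). Lower with shYB-1, beside YBX1, were RPPH1 by 4.89-fold (4.81 to 4.98), PARP2 by 4.56-fold (4.48 to 4.64), the collagen receptor subunit ITGA10 by 7.47-fold (5.26 to 10.8) and MLPH, which links melanosomes to myosin, by 4.27-fold (3.87 to 4.73). RP11-159D12.5, RP11-211G3.3 and RP11-315I20.3 had 10, 5 and 2 reads in the shYB-1 library against 35, 22 and 16 in the shScr library. AL035588.1 and AC112205.1 were listed at 0 in the shYB-1 library and had 1 and 3 reads in the shScr library, too few for a fold. Of 7296 genes, 217 were at least 2-fold higher and 176 at least 2-fold lower on the FPKM + 1 scale. With equal read totals outside the mitochondrial genome these counts were 245 and 105, and with a pseudocount of 5 they were 47 and 47. The intervals cover counting error only.

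The last comparison asked whether the effect of shYB-1 was the same in tumors and in 2D culture. With a preset correlation between genes the cell cycle lists differed, although no single gene passed. The shYB-1 effect in tumors minus that in culture had a median of -0.88 for 28 mitosis genes (limma camera adjusted p = 4.0e-09 on the interaction term; adjusted p = 0.968 with an estimated correlation), and all of them were below 0. For 18 DNA replication genes it was -0.83 (adjusted p = 1.1e-05; adjusted p = 0.968 with an estimated correlation). For 17 antigen presentation genes it was -0.51 (adjusted p = 0.0381; adjusted p = 0.968 with an estimated correlation), a call lost without shScr tumor replicate 3 (-0.41, adjusted p = 0.138, with a range of 4.0e-07 to 0.138 over the tumor libraries left out, quantile normalization and equal read totals). Adjusted over the list alone, 2 mitosis, 0 DNA replication and 4 antigen presentation genes were lower. On the FPKM + 1 scale no single gene passed the interaction test with limma: the smallest adjusted p was 0.0761 (RP11-211G3.3), while 279 genes were higher and 549 lower at an unadjusted p under 0.05. Among genes with the smallest p, HLA-DRB5 had an interaction of -2.70, SDC4 of -2.47, PIGU of -1.85, SLC7A5 of -1.80 and SAA1 of -1.62, and in the other direction MLPH of 1.88, POLG of 1.25, ACSS2 of 1.22 and AREG of 0.88, with adjusted p from 0.143 to 0.312. SAA1 and AREG stood at 0 to 0.174 FPKM in every tumor, so their values only restate the difference between the 2D libraries. The remaining 20 lists did not pass (adjusted p from 0.121), and for stress granule, unfolded protein, mitochondrial genome, immediate early and fibroblast genes the median was below 0 while the test pointed upward. The test assumes that each lone 2D library varies like the tumors, which was not checked. Its count of 0 genes depended on the setting: it called 4 genes without shYB-1 tumor replicate 2, 11 with a pseudocount of 0.1, 36 with 5, 4 without a filter and 9 with equal read totals outside the mitochondrial genome.

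Across 7456 genes, which are not independent replicates, the shYB-1 differences in tumors and in 2D culture had a Pearson r of 0.293 and a Spearman rho of 0.289, and the 2 differences share no library. Reads outside the mitochondrial genome were more numerous with shYB-1 in tumors and also in 2D culture (3999324 against 1978866). A depth effect shared by both settings therefore cannot be told apart from the hairpin. For the single shYB-1 tumors r was 0.258, 0.197 and 0.264 (replicates 1, 2 and 3). Of the genes with an unadjusted p under 0.05 in tumors that were also measured in 2D culture, 262 of 354 higher genes (74.0%) and 673 of 985 lower genes (68.3%) went the same way in culture, where 49.8% of all genes were higher. YBX1, RPPH1 and PARP2 were at least 2-fold lower in both settings. So were the tropomyosin gene TPM2 (-1.60 in tumors, -1.79 in culture), the interferon-induced membrane protein gene IFITM2 (-1.37 and -1.07) and MT-CO2 (-1.30 and -1.08), which did not pass in tumors (adjusted p from 0.159 to 0.198) and were chosen after their values were seen.

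**Figure D5:**
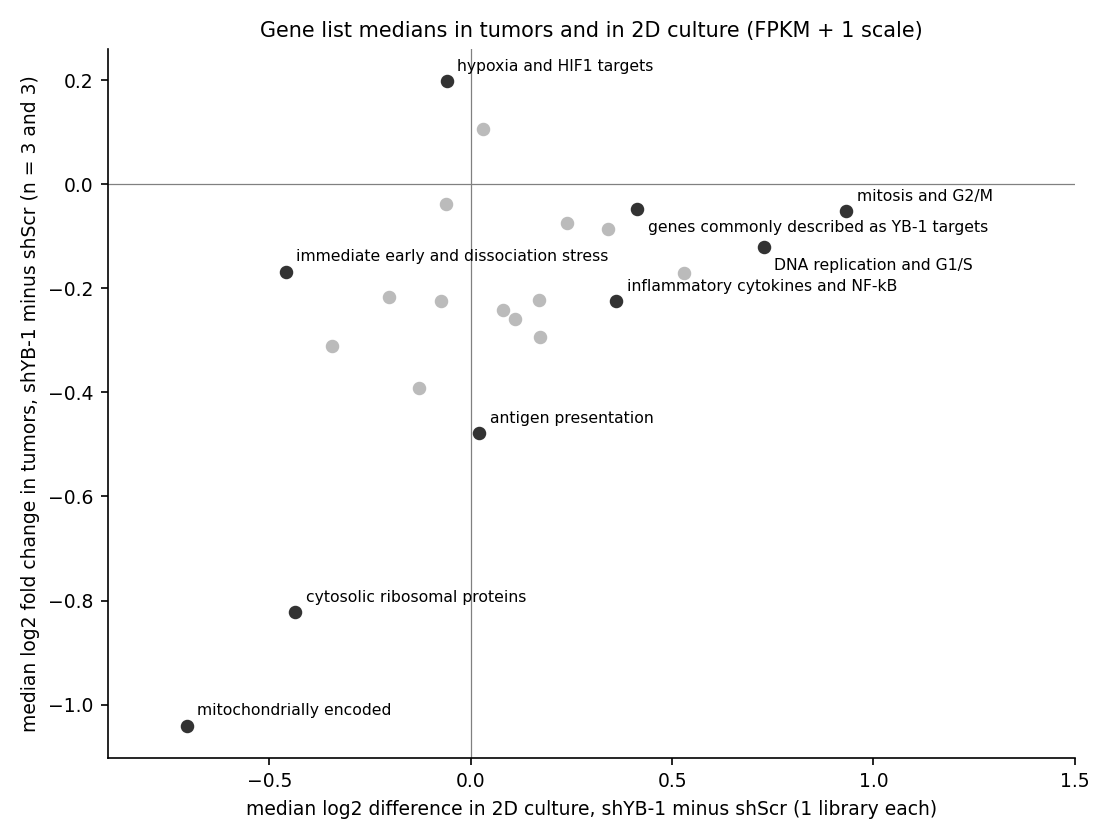
Median log2 difference of each gene list in 2D culture (shYB-1 minus shScr, 1 library each, horizontal axis) against its median log2 fold change in tumors (n = 3 each, vertical axis), both on the FPKM + 1 scale, with 1 point per list. Ribosomal protein genes lie below 0 on both axes (-0.44 and -0.82), while mitosis genes lie at 0.93 in culture and -0.05 in tumors (0.38 in tumors with equal read totals outside the mitochondrial genome).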

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

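The interaction test behind the following results was planned, whereas quantile normalization and equal read totals were chosen after the result had been seen. For 3 gene lists the shYB-1 effect differed between tumors and 2D culture by a test of the difference itself with a preset correlation, and for none with an estimated one. For mitosis genes the effect in tumors minus that in culture had a median of -0.88 (limma camera adjusted p = 4.0e-09; adjusted p = 0.968 with an estimated correlation), -0.68 under quantile normalization and -0.54 with equal read totals. With the preset correlation it kept its sign and its call with each tumor library left out (-1.01 to -0.77), and with an estimated correlation it had no call. MKI67, a marker of cycling cells, stood at 12.3 FPKM (shScr) and 16.1 FPKM (shYB-1) in 2D culture and 5.76 ± 0.931 and 5.46 ± 0.516 FPKM in tumors (SD, n = 3 each). For DNA replication genes the median was -0.83 (adjusted p = 1.1e-05; adjusted p = 0.968 with an estimated correlation), -0.68 under quantile normalization and -0.47 with equal read totals. With each tumor library left out it lay between -0.93 and -0.74 and kept its call on the same basis. For antigen presentation genes it was -0.51 (adjusted p = 0.0381; adjusted p = 0.968 with an estimated correlation), -0.22 under quantile normalization and -0.16 with equal read totals, and without shScr tumor replicate 3 the call was lost (-0.41, adjusted p = 0.138, with a range of 4.0e-07 to 0.138 over these settings). HLA-DRA, of HLA class II, stood at 3.50 FPKM (shScr) and 38.4 FPKM (shYB-1) in 2D culture and 31.4 ± 14.1 and 31.3 ± 6.34 FPKM in tumors, and CD74 at 34.5 FPKM (shScr) and 175 FPKM (shYB-1) in 2D culture and 254 ± 113 and 147 ± 49.6 FPKM in tumors. MKI67, HLA-DRA and CD74 were chosen after their values were seen. All 3 results rest on 1 shScr and 1 shYB-1 library from 2D culture, whose own spread was not measured, and no explanation was weighed for them.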

How the results depend on the processing

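Quantile normalization, equal read totals outside the mitochondrial genome and voom weights were chosen after the data had been seen; the other settings were planned. Of the values for single genes and lists, 1418 counted as unchanged, 60 came to pass, 55 ceased to pass, 18 untested values moved and 5 reversed. For a tested value unchanged meant the same direction and the same side of the threshold. A list without a call in either fit was counted as unchanged whatever its direction, and some of these lists changed direction. Of the values that answer a comparison 129 counted as unchanged, 38 moved and 3 ceased to pass. The genes lower in shYB-1 tumors numbered 4 as reported, and 1 with a pseudocount of 5 and 1 without a filter, with 92 higher and 21 lower at equal read totals. The lists called numbered 2 at a minimum of 5 FPKM and 3 in the additive fit over 8 libraries, against 5. Genes higher and lower in tumors than in 2D culture numbered 839 and 725 at a minimum of 5 FPKM, where fewer genes are tested. In the shYB-1 arm alone these genes numbered 845 and 1212. In the shScr arm alone, which holds as many libraries, they numbered 1641 and 1466. The number of libraries therefore does not account for the lower counts of the shYB-1 arm. At equal read totals 882 genes were lower in tumors than in 2D culture. In 2D culture 481 genes were 2-fold higher and 465 lower with a pseudocount of 0.1, 47 and 47 with 5, 111 and 99 at a minimum of 5 FPKM, and 105 lower at equal read totals. Interaction calls numbered 11 with a pseudocount of 0.1, 36 with 5, 4 without a filter and 9 at equal read totals. The correlation of the shYB-1 effects was 0.353 at a minimum of 5 FPKM and 0.352 under quantile normalization. The median of mitochondrially encoded genes reversed to 0.0204 in tumors (0 without shYB-1 tumor replicate 3) and to 0.0938 between tumors and culture under quantile normalization, which by construction gives the most abundant genes the same values in each library. Where nothing else is said the cause was not tested.

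With 1 library left out at a time, genes higher in shYB-1 tumors ranged from 0 to 2 and lower from 0 to 9, the YBX1 log2 fold change from -3.26 to -2.81 and the lists called from 2 to 10. The highest counts came without shYB-1 tumor replicate 2 for genes and replicate 3 for lists. The hypoxia median ranged from -0.34 (without shYB-1 tumor replicate 2) to 0.50 and the mitosis median from -0.17 (without shYB-1 tumor replicate 3) to 0.0484. Genes higher in tumors than in 2D culture ranged from 841 to 2044 and lower from 1146 to 1907, with the lowest counts without the shScr 2D library, and interaction calls from 0 to 4 (without shYB-1 tumor replicate 2). Where an arm kept 1 library, it was assumed to vary like the other groups. With the replicate number as a replicate block, 0 genes were higher and 1 lower, but deviations of tumors with the same number had correlations of -0.10, -0.02 and -0.01 and did not pair. Reads outside the mitochondrial genome, as few as 1978866 in the shScr 2D library, limit what is measured at low levels.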

Other observations

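Of the tests in this part, those on the ribosomal list without 1 library and against matched genes per library, on the ratio of RPPH1 to PARP2, on RNAs without a poly(A) tail and on the number of genes in other splits were chosen after the result had been seen, and the others before, although quantile normalization of the ribosomal list had been seen when its matched lists were planned. Of the genes listed at 0 in both 2D libraries, 9 stood at 5 FPKM or more in all 6 tumors. Beside those named among the largest increases, they were GATM, an enzyme of creatine synthesis (at least 125-fold higher in tumors against a floor of 3 reads per 2D library), SPI1, a transcription factor of myeloid cells (at least 67.3-fold), MGC4294 (at least 23.5-fold) and POTEF (at least 89.3-fold), whose value is uncertain because of near-identical copies. HLA class II genes, chosen after their values were seen, did not pass between tumors and culture: CD74 had a log2 fold change of 1.22 (limma adjusted p = 0.108) and HLA-DRA of 1.23 (adjusted p = 0.0826). Skeletal muscle genes, also chosen after their values were seen, were present in 2 shScr tumors: ACTA1 stood at 76.0 and 26.4 FPKM, DES at 15.8 and 5.03 FPKM and CKM at 6.31 and 3.31 FPKM in shScr tumor replicates 1 and 2. In the other 6 libraries these 3 genes were listed at 0 or under 0.5 FPKM. GAPDH, PGK1 and NDRG1, chosen the same way, stood at 5579.6, 518 and 384 FPKM in shYB-1 tumor replicate 2 and at 578, 73.8 and 24.2 FPKM in replicate 3 of the same arm.

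Ribosomal protein genes were lower as a list in shYB-1 tumors (median -0.82). None of 10000 random lists had a median as low, matched on mean FPKM (percentile 0) or on mean FPKM and length (percentile 0). Those lists hold unrelated genes while ribosomal genes move together, so they cannot decide on a shift by expression level or short length. Without shYB-1 tumor replicate 3 the median was -0.65 (camera adjusted p = 5.1e-19 with a preset correlation). That argues against this 1 library as the whole cause. With an estimated correlation the camera adjusted p was 0.677, and there was no call over all tumors either. A remaining hypothesis is that ribosomal protein transcripts are lower with shYB-1 at a given level: their difference from the 50 genes nearest to each member was 0.149 ± 0.194 in shYB-1 tumors and 0.478 ± 0.133 in shScr tumors (log2, SD, n = 3 each), -0.33 apart (two-sided exact permutation p = 0.2), and -0.44 apart in 2D culture. The tumor values overlapped (0.373 in shYB-1 tumor replicate 3 against 0.325 in shScr tumor replicate 1), and this statistic replaced a first form with more loosely matched genes, in which the arms had not overlapped. It cannot be told apart from chance or from a technical difference between the arms, because ribosomal genes move together, which lists of unrelated genes do not reflect, and 5 of the 10 splits of the tumor libraries called the list, with medians of up to 0.654 in size in the splits other than the real one.

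RPPH1 and PARP2 were both lower with shYB-1, in tumors and in 2D culture. The PARP2 value may be made largely of RPPH1 reads. Over the 8 libraries log2(RPPH1/PARP2) had an SD of 0.161 while log2 PARP2 had an SD of 1.81. The ratio lay between 3.03 and 3.45 in shYB-1 tumors and between 3.69 and 4.11 in shScr tumors. In 2D culture it was 3.62 with shYB-1 and 3.88 with shScr, so PARP2 did not follow RPPH1 exactly. Of the 100 genes nearest to RPPH1 in mean FPKM, 0 had a log2 fold change as low (lowest -1.52), so RPPH1 fell further than other genes of its level. It was taken up for that fall, which made such a result likely, so nothing is concluded on a shift by expression level. A test of lower capture of RNAs without a poly(A) tail used RN7SL1 and histone genes, whose median was -0.0793 over 6 genes. It cannot decide, because whether these histone transcripts lack a tail was not checked. The lowest value was -1.28 (HIST3H2A), against -3.07 for RPPH1. RN7SL1 itself varied too much (log2 fold change -0.62, SE 0.74), and its mean was higher with shYB-1 (128 ± 152 FPKM against 117 ± 20.7 FPKM). Lower RPPH1 RNA in cells with shYB-1 is 1 hypothesis beside these, and other technical explanations were not tested. The limma call for RPPH1 ended under several settings, such as a pseudocount of 5 (adjusted p = 0.065, with a range of 8.3e-11 to 0.287 over all settings tried).

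Some transcripts typical of fibroblasts and macrophages were present in tumor libraries and near 0 in 2D culture, with COL1A1 at 115 ± 10.7 FPKM in shScr tumors (SD, n = 3) and SPI1 listed at 0 in culture, in spite of the gate on EpCAM and CD298 and the depletion of mouse CD45 and CD31 cells. Host cells left after the sort are a candidate source: of abundant fibroblast transcripts under 1 FPKM in 2D culture limma called 5 of 6 higher in tumors, among them LOXL1 (3.31) and COL5A2, and of macrophage transcripts 2 of 2, SPI1 and LCP1 (2.48). These shares lay at percentiles 28.1 and 31.5 of random sets, below the bound set beforehand, but that bound was wrong: 82.6% of all genes so low in culture were called higher, and the highest percentiles the sets could reach were 68.7 and 31.5. Of the lists, 10 of 20 fibroblast and 7 of 12 macrophage genes stood above 1 FPKM in a 2D library of the cell line itself, and the abundant fibroblast gene IGFBP4 fell in tumors (-3.70) while TIMP3 rose (4.58). For these fibroblast and macrophage transcripts host cells therefore cannot be told apart from a change in the cancer cells, which was not tested. The skeletal muscle genes in shScr tumor replicates 1 and 2 were not part of that comparison, and their source was not tested either.

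The 6 tumor libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes called, 1 of the 10 splits, the real one, gave as many (4 genes; highest other 1), and at an unadjusted p under 0.05 the real split gave 1476 genes and the highest other 476. For gene lists called, 7 of the 10 splits gave as many as the real one (5 lists; highest other 9).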
